A study of Homo sapiens with 14 samples.

How the data were processed

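Total RNA from HepG2 and Hep3B cells had been isolated with an RNeasy mini kit and sequenced as paired reads of 100 bp on Illumina HiSeq or NovaSeq instruments, per the labels, which do not say which instrument read which library. The submitters' processing notes name STAR, DESeq2 and the GRCh38 (hg38) build, without versions or roles. The counting tool and the annotation release are not given in the sources used here. The deposited table holds raw counts: whole numbers per gene with 1 column per library, neither pooled nor normalised. It covers 56479 genes, of which 15420 entries have no gene name and 1237 share a name with another entry and were kept apart under their gene IDs. Every gene ID was found in GENCODE 29, which supplied the GRCh38 coordinates, transcript lengths and GC content used here. Entries without a name held at most 0.308% of the counts of a library.

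The 14 libraries form 7 groups of 2, read from the sample titles. The columns headed as Hep3B control were taken as the uncompressed transwell libraries, the only Hep3B group without columns of its own name. The labels call the libraries of a group biological replicates, and separate cultures are not otherwise described. Unless stated otherwise, p-values therefore measure the spread between labelled samples pooled over all 14 libraries, not that of the compared groups alone. Library totals ran from 21.2 M to 35.4 M counts. Where a named gene had no count in a group, a fold is a lower bound computed at 3 counts over that group. Where 1 of 2 compared groups held 1 to 3 counts, the ratio of normalised counts is given with its exact 95% interval, and an interaction is given with its counts. Such intervals and bounds cover counting error only.

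Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 19232 genes, and libraries were scaled by TMM. A quasi-likelihood model (glmQLFit with robust estimation, glmQLFTest) was fitted to all 14 libraries with 1 mean per group and 7 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 19232 genes, with a threshold of 0.05. Log2 fold changes carry the standard error from this fit. Levels are CPM, counts relative to the TMM-scaled library size, as mean ± SD of the 2 libraries of a group.

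The 4 comparisons were fixed before the data were examined, as were the gene lists, the rule for named genes and most alternatives. They were 4% PEG against isotonic medium in HepG2 on dishes, weight against no weight in HepG2 and in Hep3B on transwells, and 3% PEG against no compression in Hep3B on transwells. The direct contrast of weight and 3% PEG in Hep3B was tested as well, along with 2 interactions: the weight effect in Hep3B against HepG2, and 4% PEG on dishes against the weight on transwells in HepG2. The last of these confounds the kind of compression with the culture surface, and possibly with time and sequencing run.

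Gene groups were 40 lists (973 symbols, 971 in the table, 1 looked up under its current name) with at least 5 tested members each. They were tested in limma 3.58.1 with camera, which asks whether a list moves differently from the other genes, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 40 lists. Camera with an estimated correlation and fry were alternatives. All of these list tests drew on the spread of all 14 libraries. Member counts are given over all genes tested and, where they differ, adjusted over the list alone. For no list past the threshold did median, mean and camera direction differ in sign.

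Genes named in the text follow a rule. It takes the 8 largest rises and 8 largest falls of each comparison with an adjusted p under 0.05. Such genes also need a mean of at least 5 CPM over all libraries compared and both treated libraries beyond both controls. It adds up to 4 members with the smallest p of each list past the threshold. From the hyperosmotic, mesenchymal, anti-apoptotic and pro-apoptotic lists it takes 2 members in any case. RB1, AFP and ALB were added as a check of the line labels. The rule also takes up to 10 genes changed in the same direction in all 4 comparisons, and 5 genes per direction for the other contrasts. Some genes that the rule picks are not reported here.

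Alternatives were RLE size factors, no low-count filter, a stricter filter (5 CPM in 2 libraries), the groups of a comparison fitted alone, DESeq2 1.42.0, a replicate term, a minimum log2 fold change of 1, and leaving out each library in turn. With 1 library left out, the remaining library of its group is assumed to vary like the other groups. Another 3 alternatives were added after the data had been seen: a fit without mitochondrially encoded genes, fits of dish and transwell libraries on their own, and list tests of the difference between the PEG effects. On simulated data with 200 changed genes of 19232, the model recovered 59% to 71% of changes at 2-fold and 97% to 100% at 4-fold, with at most 9 false calls and 0 in the wrong direction. All simulated libraries shared 1 dispersion trend. The simulation therefore does not measure false calls or recovery where dish pairs vary more than transwell pairs, as in the real data. Groups of 2 are too small for outlier tests of single libraries or for counts over other splits of the samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.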

Results

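RNA was sequenced from HepG2 and Hep3B, established lines grown from human liver tumours, in 14 libraries that form 7 groups of 2. HepG2 cells on culture dishes were kept in isotonic medium or for 5 days in medium with 4% polyethylene glycol 300 (PEG), a solute that raises osmolarity. HepG2 cells on transwells, culture inserts with a porous membrane, were left uncompressed or placed under a weight. Hep3B cells on transwells were left uncompressed, placed under a weight or given 3% PEG. The comparisons ask how liver cancer cells adjust their gene expression under osmotic or mechanical compression. Cell volume is not part of these data. The size of the weight and the time on transwells are not given in the sources used here. Total counts of replicates 1 and 2 were 35.4 M and 25.8 M for isotonic HepG2, 30.6 M and 28.2 M for 4% PEG, 25.4 M and 27.0 M for uncompressed HepG2 and 26.5 M and 24.0 M for HepG2 under the weight. The Hep3B libraries held 25.3 M and 25.8 M counts uncompressed, 23.7 M and 22.1 M under the weight and 21.2 M and 23.7 M in 3% PEG. Levels are given in CPM as mean ± SD (n = 2), and a value with ± and no unit is a log2 fold change with its standard error.

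The lines differed in RB1 and AFP. RB1 (ENSG00000139687, chromosome 13, 48303726 to 48599436) is a tumour suppressor that Hep3B is known to lack in working form. It stood at 127 ± 6.17 CPM in uncompressed HepG2 and 2.68 ± 0.0661 CPM in uncompressed Hep3B. AFP, the fetal serum protein alpha-fetoprotein, was at 22599 ± 239.7 CPM in HepG2 and 637 ± 0.0675 CPM in Hep3B. The first principal component, with 71.2% of the variance, parted the lines. The next, with 14.4%, set HepG2 in 4% PEG apart from the other HepG2 groups. Replicates were closer on transwells, where the biological coefficient of variation of a pair was 0.0434 to 0.0704. On dishes it was 0.323 for isotonic medium and 0.290 for 4% PEG, and replicate differences followed the GC content of transcripts (Spearman rho across genes -0.642 and -0.652). Estimated over all 14 libraries together, as in the tests of single genes, the common value was 0.168. If dish replicates are unpaired, standard errors and p-values of single genes therefore tend to be too small for 4% PEG. Replicate differences of the dish groups correlated at 0.633 across genes, so part of them may cancel between isotonic medium and 4% PEG. The labels do not pair libraries, and the fit has no replicate term. On transwells, standard errors and p-values of single genes tend to be too large. The list tests also drew on all 14 libraries, as did the estimated correlation between members of a list. On transwells, a list that did not hold with an estimated correlation may therefore reflect the dish pairs, which was not tested.

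**Figure D1:**
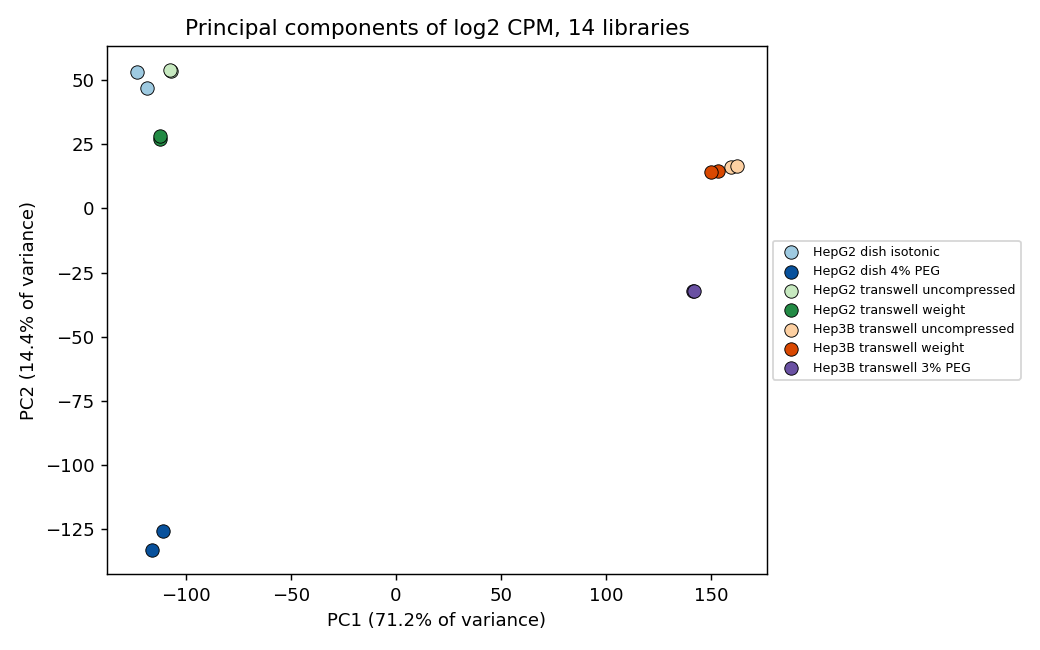
Principal components of log2 CPM for the 14 libraries, with PC1 (71.2% of the variance) on the x axis and PC2 (14.4%) on the y axis, in the scores' own units. Each point is a library, coloured by group, and PC1 separates HepG2 from Hep3B.

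HepG2 cells after 5 days in 4% PEG were compared with cells in isotonic medium, which asks what osmotic compression does to this line. Genes for dividing, for copying DNA and for building ribosomes fell, and so did the serum proteins that mark HepG2 as liver. Most genes for matrix proteases and the lysosome rose, and so did some for calcium signalling and actin. Among death genes, FAS and CASP8 rose while BIRC5 and BNIP3 fell. Every mitotic gene tested fell, 32 of 32, with a median log2 fold change of -5.52 (camera adjusted p = 7.07e-25, and adjusted p = 0.184 with an estimated correlation). CDK1 (ENSG00000170312, chromosome 10, 60778331 to 60794852), the kinase that drives entry into mitosis, dropped to 0.371 ± 0.284 CPM against 82.6 ± 15.5 CPM. Its change was -7.76 ± 0.30 (adjusted p = 7.82e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the test used for single genes throughout). TOP2A, which untangles DNA, changed by -7.51 ± 0.53 and PLK1, a mitotic kinase, by -5.32 ± 0.16. BIRC5 (survivin), a chromosome passenger protein that also blocks caspases, changed by -7.35 ± 0.24. Of 33 DNA replication genes 30 fell and none rose, with a median of -2.74 (camera adjusted p = 1.25e-16, and adjusted p = 0.155 with an estimated correlation). RRM2, a subunit of the enzyme that makes DNA building blocks, was at -6.05 ± 0.27 and MCM3 of the replicative helicase at -2.75 ± 0.11. Cytosolic ribosomal protein genes fell in 55 of 56 cases, with a median of -1.43 (camera adjusted p = 1.19e-20, and adjusted p = 0.166 with an estimated correlation). RPL15 of this group changed by -2.07 ± 0.13.

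Transcripts for the secreted proteins of liver cells fell in the same libraries. ALB (ENSG00000163631, chromosome 4, 73397114 to 73421412), the gene of serum albumin, dropped to 2920.5 ± 485 CPM against 54124 ± 402 CPM (-4.21 ± 0.13, adjusted p = 2.55e-09). AFP changed by -3.68 ± 0.19 and TF, the iron carrier transferrin, by -3.10 ± 0.15. The 10 most abundant genes took 17.6% and 17.5% of the counts in the isotonic libraries, and 10.1% and 9.12% in 4% PEG. Of 37 hepatocyte genes 24 fell and 3 rose. Their median was -1.07, or -1.15 without 1 gene near 0 counts in both groups (camera adjusted p = 6.33e-06, and adjusted p = 0.326 with an estimated correlation). ARG1, the last enzyme of the urea cycle, changed by -7.62 ± 0.26. Acute phase genes fell in 16 of 20 cases and rose in 1, with a median of -1.97 (camera adjusted p = 2.19e-06, and adjusted p = 0.184 with an estimated correlation). A2M, a protease inhibitor of plasma, changed by -2.86 ± 0.11. Fatty acid oxidation genes fell in 12 of 22 cases and rose in 1. The list median was -0.78, or -0.90 without 3 genes near 0 counts in both groups (camera adjusted p = 0.00365, and adjusted p = 0.155 with an estimated correlation). The lipid droplet coat gene PLIN2 was at -3.16 ± 0.16 and the fatty acid binding protein FABP1 at -2.60 ± 0.18. Cholesterol synthesis genes fell in 17 of 25 cases and rose in 1, with a median of -0.86 (camera adjusted p = 0.000339, and adjusted p = 0.249 with an estimated correlation). HMGCS1, an early enzyme of that pathway, changed by -1.48 ± 0.18.

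Other genes rose from near silence in 4% PEG. SEL1L3 (ENSG00000091490, chromosome 4, 25747427 to 25863760) reached 159.9 ± 30.4 CPM against 0.365 ± 0.0156 CPM (8.76 ± 0.21, adjusted p = 6.61e-10), and LAIR2, a soluble collagen receptor, reached 109 ± 36.5 CPM against 0.224 ± 0.184 CPM. NNMT, nicotinamide N-methyltransferase, had 1059 counts in 4% PEG and 0 in isotonic medium and was at least 287-fold higher. Among 22 extracellular proteases and inhibitors 16 rose and 3 fell, or 17 and 3 adjusted over the list alone, with a median of 2.23 (camera adjusted p = 9.64e-06, and adjusted p = 0.155 with an estimated correlation). MMP14, a membrane protease that cleaves matrix, was at 3.11 ± 0.20. Of the metalloprotease inhibitors, TIMP2 was at 3.60 ± 0.14 and TIMP3 at -1.83 ± 0.11. Calcium signalling genes rose in 13 of 26 cases and fell in 1, with a median of 0.53 (camera adjusted p = 0.00808, and adjusted p = 0.155 with an estimated correlation). S100A11 (ENSG00000163191, chromosome 1, 152032506 to 152047907), a calcium-binding protein, rose by 5.73 ± 0.16 to 243 ± 28.3 CPM. Actin cytoskeleton genes rose in 17 of 37 cases and fell in 3, or 19 and 3 adjusted over the list alone, with a median of 0.51 (camera adjusted p = 0.00808, and adjusted p = 0.326 with an estimated correlation). EZR and MSN, linkers of actin to the membrane, stood at 1.62 ± 0.097 and 4.46 ± 0.23.

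Lists of lysosomal, oxidant defence, heat shock and immediate early genes shifted up in 4% PEG, while the ER chaperone and ATF4 lists did not pass. Lysosome and autophagy genes rose in 19 of 30 cases and fell in 1, or 21 and 1 adjusted over the list alone, with a median of 0.72 (camera adjusted p = 0.000252, and adjusted p = 0.378 with an estimated correlation). The lysosomal protease CTSB stood at 5725 ± 2055 CPM against 952 ± 239 CPM. NRF2 targets, genes of the oxidant defence, rose in 13 of 25 cases and fell in 4, or 15 and 4 adjusted over the list alone. Their median stood at 0.80, or 0.78 without 1 gene near 0 counts in both groups (camera adjusted p = 0.0143, and adjusted p = 0.48 with an estimated correlation). Without replicate 2 of 4% PEG the NRF2 call ended (camera adjusted p = 0.0861). GCLC, which makes glutathione's precursor, stood at 2.23 ± 0.13. Cytosolic heat shock genes rose in 10 of 20 cases and fell in 3, or 11 and 3 adjusted over the list alone, with a median of 0.72 (camera adjusted p = 0.0173, and adjusted p = 0.378 with an estimated correlation). Immediate early genes, which respond quickly to growth signals, rose in 13 of 26 cases and fell in 6, with a median of 0.59 (camera adjusted p = 0.0462, and adjusted p = 0.249 with an estimated correlation). That call ended without replicate 1 of isotonic medium or replicate 1 of 4% PEG (camera adjusted p up to 0.0868). DUSP5, a phosphatase that restrains ERK, stood at 6.29 ± 0.27. ER chaperones rose in 4 of 22 cases and fell in 9, or 4 and 10 adjusted over the list alone (median -0.31, camera adjusted p = 0.112). ATF4 targets rose in 12 of 30 cases and fell in 3 (median 0.23, camera adjusted p = 0.115). Hypoxia and glycolysis genes went the other way, with 25 falls and 4 rises among 35, or 26 and 4 adjusted over the list alone, and a median of -1.10 (camera adjusted p = 9.7e-05, and adjusted p = 0.378 with an estimated correlation). The glycolytic enzymes PGK1 and ENO1 changed by -1.61 ± 0.11 and -1.55 ± 0.12, while CA12, a carbonic anhydrase, rose to 56.6 ± 3.76 CPM against 1.05 ± 0.579 CPM.

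Mitochondrial transcripts parted by genome in 4% PEG. Of 39 nuclear genes of oxidative phosphorylation 18 fell and 2 rose, with a median of -0.33 (camera adjusted p = 0.00365, and adjusted p = 0.48 with an estimated correlation). Scaling by total counts alone puts the median of all genes at 0.37 in this comparison, further from 0 than this list, so its direction holds relative to other genes. Of 13 mRNAs encoded in mitochondria 11 rose and none fell, or 12 rises adjusted over the list alone, with a median of 1.72 (camera adjusted p = 0.0181, and adjusted p = 0.653 with an estimated correlation). The call on them ended without replicate 2 of isotonic medium or replicate 1 of 4% PEG (camera adjusted p up to 0.154). Mitochondrial transcripts made up 1.87% and 0.999% of the counts in isotonic medium and 7.34% and 5.05% in 4% PEG. Replicate 1 had the higher share in each of the 7 groups.

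Genes of cell death and invasion moved both ways in 4% PEG. Pro-apoptotic genes rose in 14 of 29 cases and fell in 2, with a median of 0.48 (camera adjusted p = 0.0336, and adjusted p = 0.326 with an estimated correlation). The call ended without replicate 1 of isotonic medium or replicate 2 of 4% PEG (camera adjusted p up to 0.173). The death receptor FAS stood at 2.59 ± 0.28 and the initiator caspase CASP8 at 1.41 ± 0.16, against -1.90 ± 0.14 for BNIP3, a mitophagy and death protein. Among 16 anti-apoptotic genes 6 rose and 4 fell, and the list did not pass (camera adjusted p = 0.422). MCL1, which restrains the pore-forming protein BAK, was at 1.39 ± 0.094. Mesenchymal genes rose in 5 of 16 cases and fell in 5, or 6 and 5 adjusted over the list alone (camera adjusted p = 0.748). The fibronectin receptor subunit ITGA5 was at 6.31 ± 0.46 and the collagen cross-linker LOX at -3.67 ± 0.19. Hyperosmotic response genes rose in 8 of 14 cases and fell in 2 (camera adjusted p = 0.0908). The water and glycerol channel AQP3 was at 3.99 ± 0.24 and SGK1, a kinase regulated by osmolarity, at -4.13 ± 0.18. In total 9011 of 19232 genes (46.9%) changed in 4% PEG, 4590 up and 4421 down, and 5831 of them by at least 1 on the log2 scale. Fitted on the 4 dish libraries alone, whose replicates differ more than the pooled spread assumes, 3764 genes passed, of which 3727 were among the 9011. With a replicate term in the fit of all libraries 12307 passed, including 8988 of the 9011. That term takes libraries of the same number as pairs, which the labels do not state. Of 18 lists past camera's threshold none held with an estimated correlation, where the smallest adjusted p was 0.155, and fry passed 32 lists.

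The weight on HepG2 cells asks what a mechanical load does to the same line on transwells. Genes for copying DNA and for mitosis fell. Some genes of the extracellular matrix and of TGF-beta signalling rose. So did the growth factor binding protein IGFBP3, the collagen cross-linker LOXL2 and the orphan receptor GPRC5A. Some genes for making cholesterol and for folding secreted proteins fell. Of 33 DNA replication genes 24 fell, or 30 adjusted over the list alone, and none rose, with a median of -0.81 (camera adjusted p = 2.75e-16, and adjusted p = 0.0555 with an estimated correlation). Mitotic genes fell in 21 of 32 cases, or 32 adjusted over the list alone, with a median of -1.02 (camera adjusted p = 9.55e-16, and adjusted p = 0.211 with an estimated correlation). PLK1 (ENSG00000166851, chromosome 16, 23677656 to 23690367) dropped to 61.1 ± 1.38 CPM against 134 ± 4.16 CPM (-1.13 ± 0.12, adjusted p = 0.000245). CDC6, which loads the replicative helicase, changed by -1.58 ± 0.18 and BIRC5 by -1.35 ± 0.16. The list of cell cycle inhibitors and senescence genes also holds the cyclins CCND1, CCND2 and CCND3, so its shift is not one of inhibitors alone. Its members rose in 8 of 20 cases and fell in 2, or 10 and 3 adjusted over the list alone. The median was 0.41, or 0.44 without 1 gene near 0 counts in both groups (camera adjusted p = 0.00277, and adjusted p = 0.0555 with an estimated correlation). CDKN2B, the inhibitor p15 of CDK4 and CDK6, rose by 1.51 ± 0.20. IGFBP3 (ENSG00000146674, chromosome 7, 45912245 to 45921874) reached 190.0 ± 4.82 CPM against 20.4 ± 2.94 CPM (3.22 ± 0.30, adjusted p = 8.74e-05).

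Lists of signalling and matrix genes shifted up in HepG2 under the weight. TGF-beta response genes rose in 11 of 22 cases, or 16 adjusted over the list alone, and none fell. Their median was 0.73, or 0.74 without 1 gene near 0 counts in both groups (camera adjusted p = 5.48e-08, and adjusted p = 0.0555 with an estimated correlation). LTBP2, a matrix relative of the proteins that store latent TGF-beta, was at 2.42 ± 0.24. YAP and TEAD targets rose in 7 of 20 cases, or 10 with 1 fall adjusted over the list alone, and had a median of 0.47 (camera adjusted p = 4.84e-05, and adjusted p = 0.104 with an estimated correlation). Among them the receptor kinase AXL was at 2.28 ± 0.20 and ANKRD1 at 1.69 ± 0.23. Collagens, laminins and integrins rose in 6 of 26 cases, or 10 with 1 fall adjusted over the list alone, and had a median of 0.58, or 0.60 with genes near 0 counts at their bounds (camera adjusted p = 7.05e-05, and adjusted p = 0.0555 with an estimated correlation). COL1A1 was at 2.58 ± 0.26 and ITGA3, a subunit of a laminin receptor, at 3.02 ± 0.35. Proteases and inhibitors rose in 6 of 22 cases, or 7 adjusted over the list alone, with a median of 0.61 (camera adjusted p = 5.27e-05, and adjusted p = 0.0555 with an estimated correlation). Mesenchymal genes rose in 5 of 16 cases, or 6 with 1 fall adjusted over the list alone, and had a median of 0.79, or 0.70 with genes near 0 counts at their bounds (camera adjusted p = 0.00108, and adjusted p = 0.0555 with an estimated correlation). LOXL2 (ENSG00000134013, chromosome 8, 23297189 to 23425328) rose to 25.7 ± 2.26 CPM against 2.47 ± 0.223 CPM (3.38 ± 0.28). Epithelial junction and keratin genes rose too, in 9 of 26 cases with 1 fall, or 9 and 2 adjusted over the list alone, with a median of 0.47 (camera adjusted p = 0.0133, and adjusted p = 0.073 with an estimated correlation). Without replicate 2 under the weight this call ended (camera adjusted p = 0.0552). KRT19, a keratin of bile duct and progenitor cells, was at 1.71 ± 0.26. Actin genes rose in 7 of 37 cases and fell in 1, or 10 and 2 adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.0115, and adjusted p = 0.301 with an estimated correlation). MSN stood at 4.11 ± 0.20 and TAGLN2, an actin-binding protein, at 2.59 ± 0.28.

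Lists of early response, hypoxia and inflammatory genes also shifted up in HepG2 under the weight. Immediate early genes rose in 11 of 26 cases and fell in 2, or 13 and 3 adjusted over the list alone, with a median of 0.54 (camera adjusted p = 0.00208, and adjusted p = 0.0555 with an estimated correlation). JUN, a subunit of the transcription factor AP-1, was at 1.10 ± 0.12. Hypoxia and glycolysis genes rose in 10 of 35 cases, or 13 adjusted over the list alone, with a median of 0.26 (camera adjusted p = 7.43e-05, and adjusted p = 0.34 with an estimated correlation). EGLN3, an oxygen sensor that is itself induced in hypoxia, stood at 2.85 ± 0.16 and VEGFA, a growth factor for blood vessels, at 1.40 ± 0.16. Acute phase genes rose in 8 of 20 cases and fell in 1, or 11 and 2 adjusted over the list alone, with a median of 0.37 (camera adjusted p = 0.00632, and adjusted p = 0.335 with an estimated correlation). Complement C3 was at 1.34 ± 0.14. NF-kB and inflammatory genes rose in 3 of 21 cases, or 7 with 1 fall adjusted over the list alone, and had a median of 0.86, or 0.45 with genes near 0 counts at their bounds (camera adjusted p = 0.0105, and adjusted p = 0.116 with an estimated correlation). Without replicate 1 under the weight the NF-kB call ended (camera adjusted p = 0.129), and the cytokine IL18 was at 3.20 ± 0.32. Stem and progenitor genes rose in 6 of 25 cases and fell in 3, or 9 and 3 adjusted over the list alone, with a median of 0.12, or 0.18 with genes near 0 counts at their bounds (camera adjusted p = 0.037, and adjusted p = 0.215 with an estimated correlation). That call ended without uncompressed replicate 1 or weight replicate 2 (camera adjusted p up to 0.0775). CD24, a surface glycoprotein of progenitor cells, stood at 2.18 ± 0.14 and the fetal growth factor IGF2 at 1.13 ± 0.15. Endothelial markers rose in 1 of 6 cases, or 4 adjusted over the list alone, with a median of 1.18 (camera adjusted p = 0.000389, and adjusted p = 0.0555 with an estimated correlation). TIE1, an endothelial receptor, reached 6.21 ± 0.458 CPM against 0.841 ± 0.136 CPM.

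Lists of lipid synthesis and ER chaperone genes shifted down in HepG2 under the weight, with most members short of the threshold. Cholesterol synthesis genes fell in 7 of 25 cases, or 9 adjusted over the list alone, with a median of -0.46 (camera adjusted p = 4.84e-05, and adjusted p = 0.116 with an estimated correlation). ACAT2, a cytosolic thiolase that supplies the pathway, dropped to 234 ± 15.6 CPM against 468 ± 6.23 CPM. Fatty acid synthesis genes fell in 3 of 20 cases and rose in 1, or 6 and 1 adjusted over the list alone. The list median was -0.45, or -0.47 without 1 gene near 0 counts in both groups (camera adjusted p = 0.0187, and adjusted p = 0.554 with an estimated correlation). Without replicate 1 under the weight this call ended (camera adjusted p = 0.123). GPAM, which starts triglyceride synthesis, stood at -1.06 ± 0.13. ER chaperone genes fell in 5 of 22 cases, or 7 adjusted over the list alone, with a median of -0.25 (camera adjusted p = 0.0005, and adjusted p = 0.0555 with an estimated correlation). SEC61B, part of the channel into the ER, was at -0.65 ± 0.11, while the calls on DNAJC3, HYOU1 and MANF ended without any 1 of the 4 libraries (adjusted p up to 0.216). Nuclear oxidative phosphorylation genes fell in 3 of 39 cases, with a median of -0.28 (camera adjusted p = 4.84e-05, and adjusted p = 0.335 with an estimated correlation). Each of these calls, on ATP5F1A, ATP5MC1 and NDUFB3, ended without any 1 of the 4 libraries (adjusted p up to 0.213). GSTA1, a glutathione transferase of liver, changed by -2.89 ± 0.29 and SGK1 by -1.79 ± 0.16. GPRC5A (ENSG00000013588, chromosome 12, 12890782 to 12917937) rose by 3.92 ± 0.23 (adjusted p = 5.75e-06) and L1CAM, an adhesion molecule of neurons and invasive tumours, by 3.48 ± 0.32. Of 16 anti-apoptotic genes 1 rose and 1 fell, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.791). Of 29 pro-apoptotic genes 2 rose, or 1 adjusted over the list alone (camera adjusted p = 0.902). BMF, a BH3-only death protein, was at 1.06 ± 0.22, a call that ended without either uncompressed replicate or weight replicate 1 (adjusted p up to 0.102). Hyperosmotic response genes rose in 1 and fell in 1 of 14 cases (camera adjusted p = 0.744).

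Under the weight 1842 of 19232 HepG2 genes (9.58%) changed, 1038 up and 804 down, and 900 of them (723 up and 177 down) by at least 1 on the log2 scale. Rises made up 56.4% of the calls, against 64.1% with RLE size factors, and the 4 libraries fitted alone gave 3556 up and 3416 down. With a replicate term the balance turned to 2924 up and 3361 down. Leaving out any 1 of the 4 HepG2 transwell libraries gave between 480 (without uncompressed replicate 2) and 692 (without weight replicate 2), and with these 4 libraries fitted alone 6972 genes passed, including 1764 of the 1842. Of 20 lists past camera's threshold none held with an estimated correlation, where the smallest adjusted p was 0.0555, and fry passed 24 lists.

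**Figure D2:**
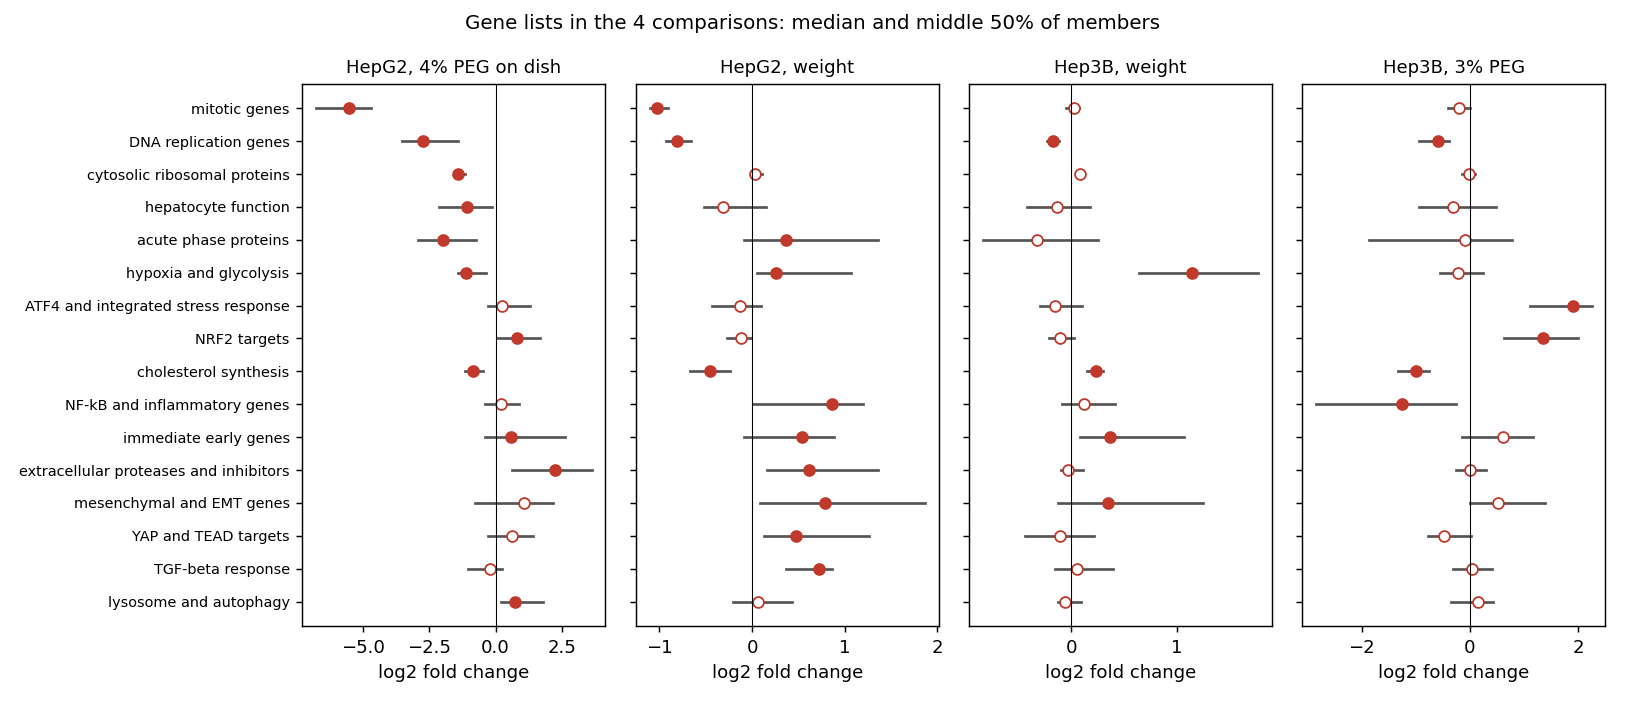
Log2 fold change (x axis) of the tested members of 16 gene lists (y axis) in each of the 4 comparisons. Dots are medians, bars span the middle 50% of members, and filled dots passed camera at an adjusted p under 0.05, such as the mitotic list at -5.52 in HepG2 in 4% PEG.

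Hep3B cells under a weight show how another line answers the load. CA9, PDK1, BNIP3 and DDIT4, known targets of the factors that respond to low oxygen, rose with many others of their kind. IGFBP1, a binding protein of insulin-like growth factors, rose from a low level. Of 35 hypoxia and glycolysis genes 18 rose and none fell, or 30 rises adjusted over the list alone, with a median of 1.14, or 1.21 with genes near 0 counts at their bounds (camera adjusted p = 2.42e-44, and adjusted p = 0.0289 with an estimated correlation). CA9 (ENSG00000107159, chromosome 9, 35673856 to 35681159), a carbonic anhydrase of the cell surface, reached 32.1 ± 9.94 CPM against 1.17 ± 0.120 CPM (4.77 ± 0.43, adjusted p = 0.000263). PDK1 (ENSG00000152256, chromosome 2, 172555373 to 172608669), a kinase that inhibits pyruvate dehydrogenase, rose by 2.05 ± 0.18 (adjusted p = 0.000263). BNIP3L, a mitophagy receptor, rose by 1.78 ± 0.15 and BNIP3 by 1.42 ± 0.14. DDIT4, an inhibitor of mTORC1, rose by 2.37 ± 0.18. IGFBP1 reached 15.7 ± 5.16 CPM against 0.648 ± 0.0267 CPM (4.59 ± 0.32).

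Immediate early genes rose in 4 of 26 cases in Hep3B under the weight, or 9 adjusted over the list alone, and none fell. Their median stood at 0.36, or 0.37 without 1 gene near 0 counts in both groups (camera adjusted p = 3.85e-08, and adjusted p = 0.0222 with an estimated correlation). IER3, an early response gene of survival and stress, stood at 1.63 ± 0.15. Mesenchymal genes rose in 2 of 16 cases and fell in 1, or 4 and 2 adjusted over the list alone. The list median was 0.34, or 0.33 without 1 gene near 0 counts in both groups (camera adjusted p = 0.00399, and adjusted p = 0.0785 with an estimated correlation). LOX was at 1.51 ± 0.18. The falling member was CDH2 (N-cadherin) at -0.76 ± 0.11, a call that ended without either uncompressed replicate or weight replicate 2 (adjusted p up to 0.109). Cholesterol synthesis genes shifted up as a list with 0 members past edgeR's test over all genes, or 2 rises adjusted over the list alone, and a median of 0.23 (camera adjusted p = 0.00136, and adjusted p = 0.382 with an estimated correlation). ER chaperones did so with a median of 0.17 (camera adjusted p = 0.00468, and adjusted p = 0.0785 with an estimated correlation). DNA replication genes shifted down with a median of -0.17 (camera adjusted p = 0.00342, and adjusted p = 0.526 with an estimated correlation), and nuclear oxidative phosphorylation genes with a median of -0.13 (camera adjusted p = 0.00342, and adjusted p = 0.609 with an estimated correlation). The last of these calls ended without replicate 2 under the weight (camera adjusted p = 0.214). Mitotic genes had a median of 0.028 and did not pass (camera adjusted p = 0.864). The anti-apoptotic, pro-apoptotic and hyperosmotic lists did not pass either (camera adjusted p = 0.197, 0.822 and 0.105). TNFRSF10D, a decoy receptor for the death ligand TRAIL, was at 0.87 ± 0.12, and its call ended without either uncompressed replicate or weight replicate 2 (adjusted p up to 0.124). The bile acid enzyme AKR1D1 was at -1.17 ± 0.19, and its call ended without any 1 of the 4 libraries (adjusted p up to 0.163).

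Under the weight 202 of 19232 Hep3B genes (1.05%) changed, 169 up and 33 down, and 1618 had an unadjusted p under 0.05. Leaving out any 1 of the 4 libraries gave between 38 genes (without uncompressed replicate 2) and 120 (without weight replicate 1). DESeq2 passed 488 genes, edgeR without a low-count filter 456, and edgeR on the 4 libraries alone 2474 (57.6% of them up), including 191 of the 202. Of 7 lists past camera's threshold, the hypoxia and immediate early lists held with an estimated correlation.

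**Figure D3:**
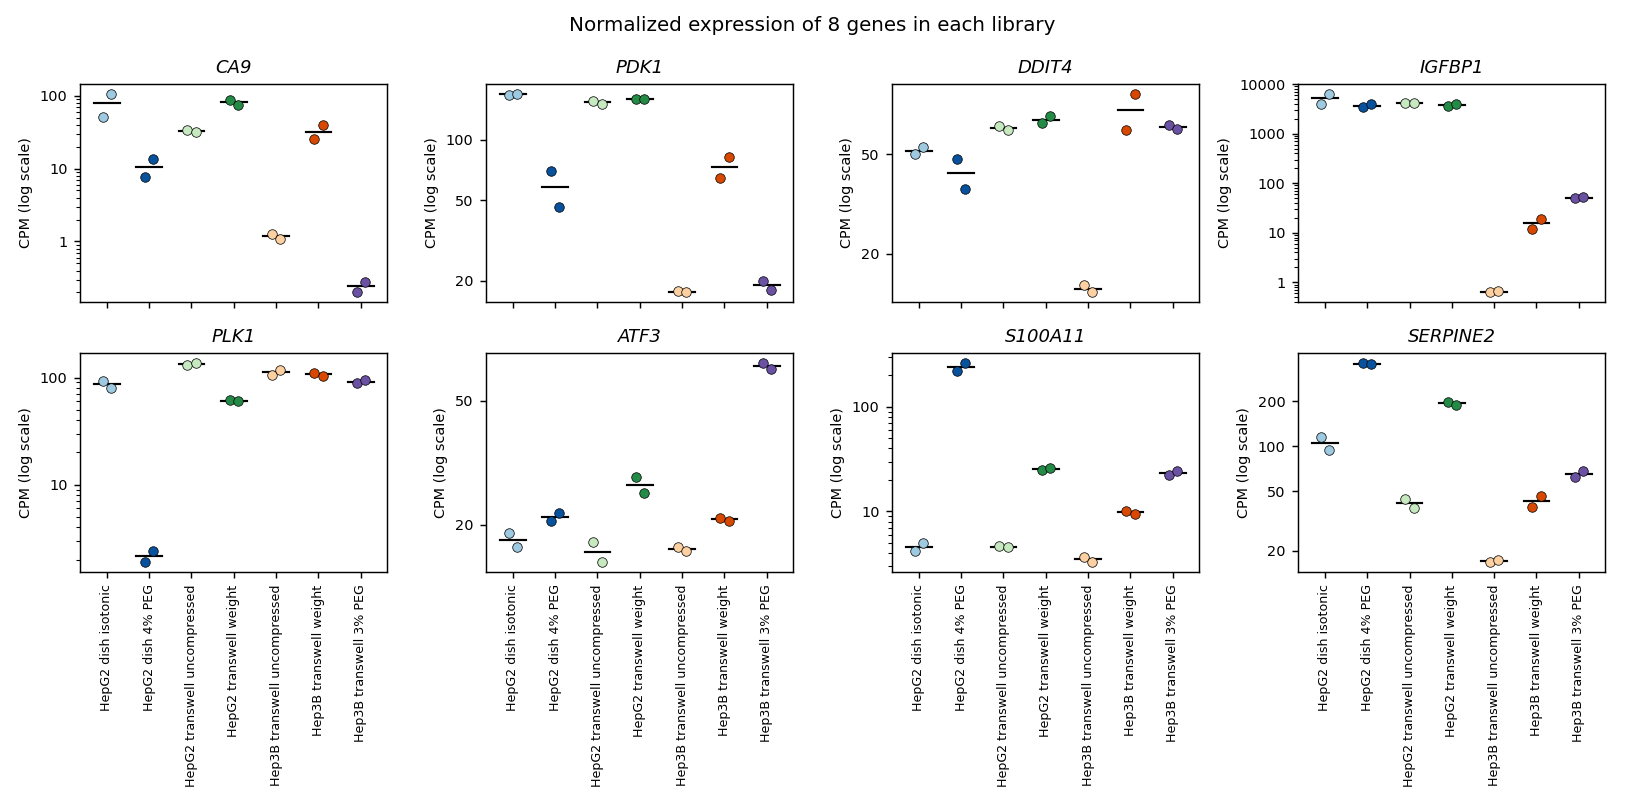
Level of 8 genes in CPM (log y axis) for each library, grouped along the x axis by the 7 groups. Points are libraries and lines are group means, and CA9 and DDIT4 stand higher in both Hep3B libraries under the weight than in both uncompressed libraries.

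The comparison of 3% PEG with no compression in Hep3B asks what osmotic compression does to this line. Stress genes driven by ATF4, the factor of the integrated stress response, and by NRF2, the factor of the oxidant defence, rose in most cases. Most genes for cholesterol synthesis fell, and so did the chemokines CXCL1 and CCL20. NIBAN1, UNC5B and SPINK1 rose from low levels, and CPS1 of the urea cycle fell. Of 30 ATF4 targets 26 rose and none fell, or 27 rises adjusted over the list alone, with a median of 1.90 (camera adjusted p = 6.78e-19, and adjusted p = 0.159 with an estimated correlation). ATF3 (ENSG00000162772, chromosome 1, 212565334 to 212620777), a stress transcription factor, reached 64.8 ± 1.84 CPM against 16.7 ± 0.295 CPM (1.95 ± 0.13, adjusted p = 3.39e-06). STC2, a secreted glycoprotein, stood at 2.81 ± 0.20 and MTHFD2, a mitochondrial folate enzyme, at 1.45 ± 0.098. NRF2 targets rose in 19 of 25 cases and fell in 1, or 19 and 2 adjusted over the list alone, with a median of 1.35 (camera adjusted p = 6.54e-11, and adjusted p = 0.159 with an estimated correlation). GCLC (ENSG00000001084, chromosome 6, 53497341 to 53616970) reached 309 ± 1.98 CPM against 62.7 ± 0.860 CPM (2.30 ± 0.13) and NQO1, a quinone reductase, was at 1.81 ± 0.14. Interferon-stimulated genes rose in 7 of 29 cases and none fell, with a median of 0.46, or 0.42 with genes near 0 counts at their bounds (camera adjusted p = 0.00558, and adjusted p = 0.471 with an estimated correlation). The transcription factor IRF1 was at 1.85 ± 0.23. NIBAN1 (ENSG00000135842, chromosome 1, 184790724 to 184974550), a stress-induced protein, reached 44.3 ± 1.60 CPM against 0.280 ± 0.000857 CPM (7.28 ± 0.56). UNC5B, a netrin receptor, was 304-fold higher by counts (95% interval 104 to 1478). SPINK1, a trypsin inhibitor, stood at 5.12 ± 0.20 and IGFBP1 at 6.28 ± 0.32.

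Lists of lipid synthesis and inflammatory genes shifted down in Hep3B in 3% PEG. Cholesterol synthesis genes fell in 21 of 25 cases and none rose, with a median of -0.99 (camera adjusted p = 1.33e-10, and adjusted p = 0.0748 with an estimated correlation). HMGCS1 was at -1.75 ± 0.18 and NSDHL, a sterol dehydrogenase, at -1.60 ± 0.12. Fatty acid synthesis genes fell in 7 of 20 cases and rose in 3, or 8 and 3 adjusted over the list alone, with a median of -0.53 (camera adjusted p = 0.0266, and adjusted p = 0.515 with an estimated correlation). The desaturase SCD was at -1.25 ± 0.12 and ME1, which supplies NADPH, at 2.87 ± 0.23. NF-kB and inflammatory genes fell in 11 of 21 cases and none rose, or 12 falls adjusted over the list alone. Their median was -1.25, or -1.05 without 1 gene near 0 counts in both groups (camera adjusted p = 1.12e-06, and adjusted p = 0.0742 with an estimated correlation). The chemokine CXCL1 (ENSG00000163739, chromosome 4, 73869393 to 73871242) dropped to 0.885 ± 0.397 CPM against 21.4 ± 1.40 CPM (-4.57 ± 0.39, adjusted p = 2.43e-05), and CCL20 changed by -2.86 ± 0.18. CPS1 (ENSG00000021826, chromosome 2, 210477682 to 210679107), the first enzyme of the urea cycle, changed by -4.46 ± 0.14, AFP by -1.60 ± 0.17 and ALB by -0.71 ± 0.12. Hepatocyte genes as a list did not pass, with 13 falls and 7 rises among 37, or 14 and 8 adjusted over the list alone (median -0.30, camera adjusted p = 0.318).

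Genes of DNA replication and some nuclear genes of oxidative phosphorylation fell as well in 3% PEG. DNA replication genes fell in 20 of 33 cases, or 22 adjusted over the list alone, with a median of -0.59 (camera adjusted p = 8.14e-07, and adjusted p = 0.234 with an estimated correlation). UHRF1, which maintains DNA methylation, was at -1.54 ± 0.16. The mRNAs of replication-dependent histones lack poly(A) tails, so their level also depends on how libraries were prepared. Of 14 replication-dependent histone genes 9 fell, with a median of -1.75 (camera adjusted p = 1.12e-06, and adjusted p = 0.0742 with an estimated correlation). Mitotic genes fell in 2 of 32 cases, or 0 adjusted over the list alone, and the list did not pass (median -0.20, camera adjusted p = 0.242). Nuclear oxidative phosphorylation genes fell in 16 of 39 cases, or 19 adjusted over the list alone, with a median of -0.38 (camera adjusted p = 7.32e-06, and adjusted p = 0.471 with an estimated correlation). SDHA, a subunit of succinate dehydrogenase, was at -0.80 ± 0.16. The mRNAs encoded in mitochondria did not pass (median -0.12, camera adjusted p = 0.703). Stem and progenitor genes fell in 13 of 25 cases and rose in 3, or 15 and 4 adjusted over the list alone, with a median of -0.48 (camera adjusted p = 0.00521, and adjusted p = 0.166 with an estimated correlation). The fetal growth factor IGF2 was at -2.12 ± 0.15 and the transcription factor KLF4 at 5.89 ± 0.47.

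Pro-apoptotic genes rose in 6 of 29 cases and fell in 1 in 3% PEG, and 3 of 16 anti-apoptotic genes rose. Neither list passed (camera adjusted p = 0.245 for both). The death receptor TNFRSF10B stood at 1.41 ± 0.13 and the decoy receptor TNFRSF10D at 0.84 ± 0.12. Mesenchymal genes rose in 5 of 16 cases and fell in 2, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.138). The collagen cross-linker LOX was at -2.05 ± 0.19. Hyperosmotic response genes rose in 2 of 14 cases and fell in 4 (camera adjusted p = 0.686). SLC12A2, a cotransporter of sodium, potassium and chloride, was at -1.87 ± 0.22. In all 4323 of 19232 genes (22.5%) changed, 2111 up and 2212 down, and 2172 of them by at least 1 on the log2 scale. Leaving out any 1 of the 4 libraries gave between 1999 genes (without 3% PEG replicate 2) and 2143 (without uncompressed replicate 2), and 9864 passed with these 4 libraries fitted alone, including 4212 of the 4323. Of 10 lists past camera's threshold none held with an estimated correlation, where the smallest adjusted p was 0.0742, and fry passed 27 lists.

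The direct contrast in Hep3B asks which genes tell the weight from 3% PEG. Lists of hypoxia, sterol synthesis and inflammatory genes were higher under the weight, and those of ATF4 and NRF2 targets in 3% PEG. Of 35 hypoxia and glycolysis genes 28 were higher under the weight and none lower, with a median difference of 1.28 (camera adjusted p = 4.16e-14, and adjusted p = 0.171 with an estimated correlation). CA9 differed by 7.01 ± 0.53 (adjusted p = 5.9e-06). ATF4 targets were lower under the weight in 27 of 30 cases, or 28 adjusted over the list alone, with a median of -1.65 (camera adjusted p = 7.34e-19, and adjusted p = 0.16 with an estimated correlation). NRF2 targets were lower in 19 of 25, with a median of -1.60 (camera adjusted p = 1.1e-12, and adjusted p = 0.147 with an estimated correlation). Cholesterol synthesis genes were higher under the weight in 22 of 25 cases, with a median of 1.36 (camera adjusted p = 4.07e-13, and adjusted p = 0.0634 with an estimated correlation). NF-kB and inflammatory genes were higher in 12 of 21, or 14 adjusted over the list alone, with a median of 1.16 (camera adjusted p = 1.24e-08, and adjusted p = 0.0406 with an estimated correlation). Of the 14 lists past camera's threshold here, this is the only call to hold with an estimated correlation. CP, the copper carrier ceruloplasmin, stood at 631 ± 144 CPM under the weight and 10.8 ± 0.634 CPM in 3% PEG. The metallothionein MT2A differed by -5.20 ± 0.54 and SPINK1 by -5.54 ± 0.21. Between these groups 4444 genes differed, 2261 higher and 2183 lower under the weight. Leaving out any 1 of the 4 libraries gave between 2018 genes (without weight replicate 2) and 2467 (without weight replicate 1), and 9328 passed with the 4 libraries fitted alone.

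**Figure D4:**
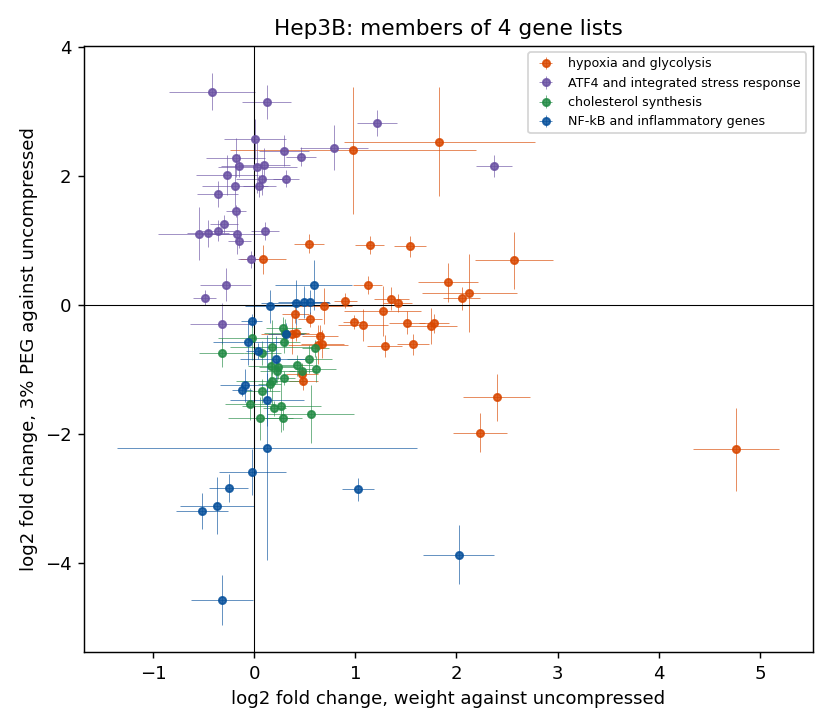
Log2 fold change of single genes in Hep3B under the weight (x axis) and in 3% PEG (y axis), each against uncompressed cells, for 4 gene lists. Bars are standard errors of the fit, and hypoxia genes spread along the weight axis while ATF4 targets spread along the 3% PEG axis.

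An interaction test asked whether the weight acted differently on the lines. Mitotic genes, which fell in HepG2, differed between Hep3B and HepG2 by a median of 1.05 (camera adjusted p = 1.56e-14, and adjusted p = 0.231 with an estimated correlation). Hypoxia and glycolysis genes were more positive in Hep3B, by a median of 0.65 (camera adjusted p = 1.24e-09, and adjusted p = 0.182 with an estimated correlation). YAP and TEAD targets were more positive in HepG2, with a median of -0.65 (camera adjusted p = 4.57e-07, and adjusted p = 0.14 with an estimated correlation). The ER chaperone list, which shifted down in HepG2, differed by 0.47 (camera adjusted p = 4.57e-07, and adjusted p = 0.0229 with an estimated correlation). UCA1, a long noncoding RNA, rose in HepG2 by 3.75 ± 0.26 and was at -1.15 ± 0.21 in Hep3B, where its call ended without any 1 of the 4 libraries (adjusted p up to 0.338). Its interaction was -4.89 ± 0.34. Interactions passed for 364 genes, 158 more positive in Hep3B and 206 more positive in HepG2. Leaving out any 1 of the 8 libraries gave between 100 genes (without HepG2 uncompressed replicate 2) and 141 (without Hep3B weight replicate 1). DESeq2 passed 843 genes, edgeR without a low-count filter 675, and edgeR on the 8 libraries alone 3733, where the balance turned to 1961 more positive in Hep3B and 1772 in HepG2.

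A further interaction compared 4% PEG on dishes with the weight on transwells in HepG2. Genes for mitosis and ribosomes were more negative in 4% PEG, and so were the lists of acute phase and TGF-beta genes, which shifted up under the weight. All 32 mitotic genes were more negative in 4% PEG, with a median difference of -4.51 (camera adjusted p = 1.02e-24, and adjusted p = 0.186 with an estimated correlation). Ribosomal protein genes were more negative in 55 of 56 cases, with a median of -1.46 (camera adjusted p = 6.66e-22, and adjusted p = 0.141 with an estimated correlation). Hypoxia and glycolysis genes were more negative in 26 of 35 cases and more positive in 3, or 28 and 3 adjusted over the list alone, with a median of -1.34 (camera adjusted p = 7.9e-08, and adjusted p = 0.324 with an estimated correlation). Acute phase genes were more negative in 17 of 20 cases, with a median of -2.44 (camera adjusted p = 3.1e-08, and adjusted p = 0.141 with an estimated correlation). TGF-beta response genes were more negative in 11 of 22 cases, with a median of -0.76 (camera adjusted p = 0.00251, and adjusted p = 0.247 with an estimated correlation). Proteases and inhibitors were more positive in 11 of 22 cases, or 12 adjusted over the list alone, with a median of 1.66 (camera adjusted p = 0.000385, and adjusted p = 0.141 with an estimated correlation). ARG1 differed by -7.50 ± 0.31 (adjusted p = 8.58e-08) and SLC6A14, an amino acid transporter, by -8.90 ± 0.44. The contrast passed for 5751 genes, 2764 more positive and 2987 more negative in 4% PEG, and for 3551 with the 8 libraries fitted alone. Compression type, culture surface and any difference in time or sequencing run cannot be separated in it.

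Genes with the same direction of call were counted across the 4 comparisons. There were 15 of them, 9 up and 6 down, while 930 genes had opposite calls somewhere. Without either uncompressed Hep3B replicate only 2 of the 15 kept all 4 calls, S100A11 and SERPINE2, and leaving out any 1 of the other libraries kept between 4 (without Hep3B weight replicate 2) and 15. The Hep3B comparisons share their control libraries, which favours calls of the same sign, and the number by chance was not computed. S100A11 rose by 5.73 ± 0.16 in HepG2 in 4% PEG, 2.47 ± 0.15 in HepG2 under the weight, 1.48 ± 0.15 in Hep3B under the weight and 2.73 ± 0.15 in Hep3B in 3% PEG. SERPINE2, an inhibitor of thrombin and plasminogen activators, rose by 1.77 ± 0.13, 2.23 ± 0.13, 1.32 ± 0.13 and 1.93 ± 0.13 in the same order. The calls on both held without each library in turn. MYOF, a membrane repair protein, stood at 5.32 ± 0.29, 3.87 ± 0.28, 1.38 ± 0.24 and 2.43 ± 0.24. Its call in Hep3B under the weight ended without either uncompressed replicate or weight replicate 2 (adjusted p up to 0.298). Values of AKR1D1 were -2.31 ± 0.20, -2.01 ± 0.20, -1.17 ± 0.19 and -1.48 ± 0.19, and its call in Hep3B under the weight ended without any 1 of the 4 libraries (adjusted p up to 0.163).

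Over all 19232 genes the effects of 4% PEG in HepG2 and 3% PEG in Hep3B correlated at r = 0.294 (Spearman rho 0.331). In both, 1128 genes rose and 1057 fell, against 504 and 508 by chance overlap. Effects of the weight in HepG2 and Hep3B correlated at r = 0.193 (rho 0.223), and at 0.121 without Hep3B weight replicate 2, with 62 shared rises against 9.12 by chance and 7 shared falls against 1.38. Within HepG2, 4% PEG and the weight correlated at r = 0.267 (rho 0.199), with 536 shared rises against 248 by chance and 466 shared falls against 185. The effects of 4% PEG in HepG2 and of the weight in Hep3B had r = 0.0387 (rho -0.0039), from 0.0044 without Hep3B weight replicate 1 to 0.0645 without Hep3B uncompressed replicate 2. They had 36 shared rises against 40.3 by chance and 19 shared falls against 7.59, and of 153 genes called in both 35.9% moved the same way. The weight in HepG2 and 3% PEG in Hep3B had r = 0.0697 (rho 0.0852), and 0.0442 without replicate 2 of 3% PEG, with 249 shared rises against 114 by chance and 230 shared falls against 92.5. Of the 756 genes called in both, 277 had opposite signs, a number whose value by chance was not computed. Over all genes 50.7% shared a sign in this pair. The weight and 3% PEG in Hep3B correlated at r = 0.304 (rho 0.250) and at 0.486 without uncompressed replicate 1. These effects share their control libraries, and simulations without any treatment effect gave 0.472 through the shared controls alone. The observed covariance exceeded the mean of 20 simulations by 0.0999, or by 0.0677 with the spread of all 14 libraries. It also lay above the highest simulated value with either spread. Fewer genes shared a sign than in the simulations (58.6% against 67.0%). Effects specific to 1 treatment lower r and sign sharing, so neither measure can decide on a common response. The covariance thus exceeded what shared controls gave in these simulations, while a common response of most genes is left open. All 6 correlations run across genes, which are not independent replicates. The 169 genes that rose under the weight in Hep3B had a median of 0.57 in HepG2 under the weight (camera adjusted p = 5.65e-17 over 24 such sets, and adjusted p = 0.0362 with an estimated correlation). The 33 falls had a median of -0.16 there (camera adjusted p = 0.0316, and adjusted p = 0.346 with an estimated correlation). In Hep3B under the weight, the 1038 HepG2 rises under the weight had a median of 0.19 (camera adjusted p = 9.97e-12, and adjusted p = 0.00885 with an estimated correlation) and the 804 falls -0.12 (camera adjusted p = 1.88e-06, and adjusted p = 0.185 with an estimated correlation). In HepG2 in 4% PEG the 169 genes had a median of -0.91 (camera adjusted p = 2.82e-05, and adjusted p = 0.232 with an estimated correlation). The 33 Hep3B falls were lower there as well, with a median of -0.89 (camera adjusted p = 0.000238, and adjusted p = 0.177 with an estimated correlation).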

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

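All tests in this part were chosen before their results were seen. Each result below is a difference between the lines in the effect of the weight, tested as an interaction and given as Hep3B minus HepG2.

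Hypoxia and glycolysis genes were more positive in Hep3B than in HepG2 under the weight, with a median interaction of 0.65 (camera adjusted p = 1.24e-09, and adjusted p = 0.182 with an estimated correlation). A bias with expression level, transcript length and GC content is excluded as the cause of the Hep3B rise, since the highest median among 10000 lists matched on these was 0.11 against the list's 1.14. A reduced oxygen supply to cells under the weight may account for it. As a test, 18 other hypoxia-induced genes outside the list had a median log2 fold change of 0.75 (camera p = 6.23e-22, and p = 0.000704 with an estimated correlation), with 6 past edgeR's adjusted threshold, all up. EPO, the hormone that liver cells make in hypoxia, is among the 18 and also among the largest interactions named below. In Hep3B it had 10 and 10 counts uncompressed and 138 and 191 under the weight, against 0 and 8 in 3% PEG. In HepG2 it had 388 and 353 counts uncompressed and 434 and 395 under the weight (0.19 ± 0.45, adjusted p = 0.871). These genes rise with the hypoxia factors whatever activates them, so the test does not tell low oxygen from another trigger. The same 18 genes had medians of 0.48 in HepG2 under the weight, -1.03 in HepG2 in 4% PEG and -0.20 in Hep3B in 3% PEG, and a response to the load that does not involve oxygen was not tested.

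Cell division and lipid genes differed in the same contrast. Mitotic genes had a median interaction of 1.05 (camera adjusted p = 1.56e-14, and adjusted p = 0.231 with an estimated correlation) and DNA replication genes 0.61 (camera adjusted p = 7.79e-11, and adjusted p = 0.14 with an estimated correlation). The list of cell cycle inhibitors and senescence genes, which also holds the cyclins CCND1, CCND2 and CCND3, was at -0.35 (camera adjusted p = 0.0231, and adjusted p = 0.143 with an estimated correlation). Cholesterol synthesis genes stood at 0.66 (camera adjusted p = 8.72e-09, and adjusted p = 0.14 with an estimated correlation) and fatty acid synthesis genes at 0.40 (camera adjusted p = 0.00113, and adjusted p = 0.336 with an estimated correlation). ER chaperones were at 0.47 (camera adjusted p = 4.57e-07, and adjusted p = 0.0229 with an estimated correlation), the only list of this contrast to hold with an estimated correlation.

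Signalling and matrix lists were more positive in HepG2. YAP and TEAD targets had a median of -0.65 (camera adjusted p = 4.57e-07, and adjusted p = 0.14 with an estimated correlation) and TGF-beta response genes -0.59 (camera adjusted p = 0.000343, and adjusted p = 0.155 with an estimated correlation). Collagens, laminins and integrins stood at -0.48 (camera adjusted p = 0.00804, and adjusted p = 0.182 with an estimated correlation), proteases and inhibitors at -0.41 (camera adjusted p = 0.000703, and adjusted p = 0.143 with an estimated correlation). Epithelial junction and keratin genes were at -0.30 (camera adjusted p = 0.0155, and adjusted p = 0.14 with an estimated correlation). Actin genes had a median of -0.076 (camera adjusted p = 0.0385, and adjusted p = 0.344 with an estimated correlation). Acute phase genes were at -0.40 (camera adjusted p = 4.14e-05, and adjusted p = 0.182 with an estimated correlation) and stem and progenitor genes at -0.21 (camera adjusted p = 0.0375, and adjusted p = 0.218 with an estimated correlation). Endothelial markers had a median of -1.68 (camera adjusted p = 0.0159, and adjusted p = 0.182 with an estimated correlation), and 4 of their 6 tested members had 3 counts or fewer in both the uncompressed and the weight group of Hep3B.

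Among genes more positive in HepG2, RND3, a small GTPase that loosens actin, had an interaction of -5.17 ± 0.50 and stood at 0.0844 ± 0.0562 CPM uncompressed and 2.83 ± 0.485 CPM under the weight in HepG2, and 79.0 ± 3.36 and 68.7 ± 2.45 CPM in Hep3B. UCA1 had -4.89 ± 0.34, at 0.775 ± 0.102 CPM uncompressed and 10.4 ± 0.346 CPM under the weight in HepG2, and 17.3 ± 1.64 and 7.79 ± 0.191 CPM in Hep3B. IGFBP3 had -3.78 ± 0.40, at 20.4 ± 2.94 CPM uncompressed and 190.0 ± 4.82 CPM under the weight in HepG2, and 86.2 ± 3.23 and 58.6 ± 2.61 CPM in Hep3B. BMP2, a growth factor, had a fitted value of -3.93 that rests on 2 counts in uncompressed HepG2 and 22 under the weight, against 1269 and 761 in Hep3B.

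Among genes more positive in Hep3B, IGFBP1 had an interaction of 4.74 ± 0.39 and stood at 4156 ± 40.3 CPM uncompressed and 3747 ± 182 CPM under the weight in HepG2, and 0.648 ± 0.0267 and 15.7 ± 5.16 CPM in Hep3B. ANGPTL2, a secreted angiopoietin relative, had 3.98 ± 0.48, at 35.9 ± 1.37 CPM uncompressed and 94.1 ± 5.99 CPM under the weight in HepG2, and 0.227 ± 0.173 and 9.61 ± 2.98 CPM in Hep3B. EPO had 3.99 ± 0.78, and its call ended without any 1 of the 8 libraries (adjusted p up to 0.155). PNCK, a calmodulin kinase, had 3.82 ± 0.85, and its call ended without any 1 of the 8 libraries except Hep3B weight replicate 1 (adjusted p up to 0.255).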

How the results depend on the processing

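Tests chosen after the data had been seen were the fits without mitochondrially encoded genes and those of dish and transwell libraries on their own. Of the named genes with a call and the correlations, 0 changed sign under the alternatives run on them, which for correlations and lists were fewer than for gene counts. Among named genes and contrasts, the same side of the threshold was kept by 368 with RLE size factors (3 lost and 2 gained a call), 365 with DESeq2 (1 and 5), 363 without a low-count filter (2 and 8), 353 with a stricter filter (4 and 4), 335 in fits of the compared groups only (8 and 28), 330 in fits of dish or transwell libraries (5 and 28) and 369 without mitochondrially encoded genes (0 and 0).

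Counts moved with the choice of libraries that are fitted together. Fits of the compared groups only gave 3764 genes in HepG2 in 4% PEG (9011 with all libraries fitted together), 6972 in HepG2 under the weight (1842), 2474 in Hep3B under the weight (202), 9864 in Hep3B in 3% PEG (4323), 9328 for weight against 3% PEG (4444), 3733 for the weight interaction (364) and 3551 for 4% PEG against the weight in HepG2 (5751). Dish or transwell libraries on their own gave 3764, 7046, 2782, 9606, 9514 and 4096 (2223 and 1873 more positive in Hep3B and in HepG2, against 158 and 206 with all libraries) for the first 6 of these. By their construction these fits, apart from that of the last contrast, no longer pool the dish pairs, with coefficients of variation of 0.290 and 0.323, with the transwell pairs at 0.0434 to 0.0704. A replicate term gave 12307, 6285, 1846, 8883, 8790, 2970 (1608 more positive in Hep3B and 1362 in HepG2) and 9730 in the same order, and 11 lists in Hep3B under the weight (7 without it). The cause was not tested. With this term 346 named genes and contrasts kept their side of the threshold, 0 lost and 27 gained a call, and HepG2 under the weight had 2924 genes up and 3361 down (1038 and 804 without it). Deviations of libraries with the same number correlated across genes at -0.0777 to 0.0732 between transwell groups, at up to 0.140 between dish and transwell groups and at 0.633 between the dish groups. The fit of the dish libraries alone counts that shared difference as spread.

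Without a low-count filter 456 genes passed in Hep3B under the weight and 675 for the weight interaction, and DESeq2 gave 488 and 843, for which the cause was not tested. A minimum log2 fold change of 1 left 5831 genes in 4% PEG, 900 in HepG2 under the weight and 2172 in 3% PEG. Camera with an estimated correlation passed 0 lists in HepG2 in 4% PEG (18 with the preset value), 0 in HepG2 under the weight (20), 2 in Hep3B under the weight (7) and 0 in 3% PEG (10). Fry passed 32, 24, 7 and 27. Camera's correlation was estimated over all 14 libraries, dish pairs included, and not on transwell libraries alone. The stricter filter tests fewer genes and moved r across genes to 0.318 for 4% PEG and the weight in HepG2, 0.0124 for 4% PEG and the weight in Hep3B, 0.328 for 4% and 3% PEG, 0.245 for the weight in both lines and 0.0498 for the weight in HepG2 and 3% PEG.

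Leaving out 1 library leaves a lone sample that is assumed to vary like the other groups. Counts then ranged from 8640 to 9349 in 4% PEG, from 480 (without uncompressed replicate 2) to 692 (without weight replicate 2) in HepG2 under the weight and from 38 (without uncompressed replicate 2) to 120 (without weight replicate 1) in Hep3B under the weight. They ranged from 1999 (without 3% PEG replicate 2) to 2143 (without uncompressed replicate 2) in 3% PEG and from 2018 (without weight replicate 2) to 2467 (without weight replicate 1) for weight against 3% PEG. The interactions ranged from 100 (without HepG2 uncompressed replicate 2) to 141 (without Hep3B weight replicate 1) for the weight and from 4093 to 6712 for 4% PEG against the weight. Lists past the threshold numbered 16 to 19 in 4% PEG, 18 to 20 in HepG2 under the weight, 7 to 10 in Hep3B under the weight and 10 to 11 in 3% PEG. Correlations ranged from 0.187 to 0.260 for 4% PEG and the weight in HepG2, 0.00435 to 0.0645 for 4% PEG and the weight in Hep3B, 0.251 to 0.284 for 4% and 3% PEG, 0.121 to 0.183 for the weight in both lines, 0.0442 to 0.0897 for the weight in HepG2 and 3% PEG, and 0.245 (without weight replicate 1) to 0.486 (without uncompressed replicate 1) for the treatments of Hep3B.

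Calls on named genes held in every such fit for 95 of 101 in 4% PEG, 59 of 96 in HepG2 under the weight, 13 of 36 in Hep3B under the weight and 73 of 76 in 3% PEG. In Hep3B under the weight 11 ended in all 4 fits, and in HepG2 under the weight 18 did. These fits still pool the spread of dish and transwell libraries, so they do not rank the comparisons by how well their calls hold. With dish or transwell libraries fitted on their own, 4 named calls were lost in HepG2 in 4% PEG. Under the weight 0 were lost in HepG2 and 0 in Hep3B, where 8 and 19 were gained. Depth limits genes near 0 counts, which are given as bounds or ratios of counts, or for the interaction of BMP2 as a fitted value with its counts.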

Other observations

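The list tests of the difference between the PEG effects were chosen after the data had been seen, and the other tests in this part were not. That contrast, 3% PEG in Hep3B minus 4% PEG in HepG2, also differs in line, dose and culture surface, and possibly in time and sequencing run. These cannot be separated. Mitotic genes, which fell in HepG2, differed by a median of 5.24 (camera adjusted p = 3.27e-29, and adjusted p = 0.14 with an estimated correlation). Ribosomal protein genes differed by 1.39 (camera adjusted p = 4.14e-22, and adjusted p = 0.14 with an estimated correlation) and DNA replication genes by 1.84 (camera adjusted p = 2.39e-13, and adjusted p = 0.112 with an estimated correlation). ATF4 targets were more positive in Hep3B by 1.11 (camera adjusted p = 1.99e-06, and adjusted p = 0.342 with an estimated correlation). Proteases and inhibitors were more positive in HepG2, with -2.06 (camera adjusted p = 2.44e-06, and adjusted p = 0.0836 with an estimated correlation), and so were YAP and TEAD targets with -1.14 (camera adjusted p = 0.00192, and adjusted p = 0.24 with an estimated correlation). The contrast passed edgeR's threshold for 4899 genes, 2481 of them more positive in Hep3B.

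The fall of mitotic and DNA replication genes in HepG2 in 4% PEG was weighed against the scaling of the libraries. Under TMM, RLE or total-count scaling the median of all genes lay at most 0.37 from 0 on the log2 scale, against -5.16 to -5.52 for the mitotic list, which excludes scaling as the cause. Fewer dividing cells in 4% PEG could explain the fall, and dividing cells were not counted. A test on 22 other cell cycle genes outside the lists gave a median of -4.67 (camera p = 1.42e-17, and p = 0.000301 with an estimated correlation), and all 22 fell. MYBL2, 1 of the 22, is also among the largest falls. These genes follow cell division whatever stops it, so the test does not tell fewer dividing cells from another cause of lower cell cycle transcripts. Their median was -0.90 in HepG2 under the weight, -0.063 in Hep3B under the weight and 0.0073 in Hep3B in 3% PEG, and whether cells arrested or died was not measured.

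Replicates 1 and 2 of the isotonic and 4% PEG groups differ from each other in the same way, with a correlation of 0.633 across genes between the groups' differences. Transcript length, as a trace of RNA degradation, showed little relation to the difference, with a Spearman rho across genes of 0.0477 in isotonic medium and -0.031 in 4% PEG. Length was not tested with GC content held equal, and RNA integrity was not examined, so degradation is not excluded. GC content had a rho of -0.642 in isotonic medium and -0.652 in 4% PEG, against -0.241 to 0.0467 in the transwell groups. A bias with GC content from library preparation or sequencing is a candidate explanation, with a batch of culture or an instrument behind it left open because the labels give neither. No biological explanation was tested.

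Mitochondrially encoded genes were higher in replicate 1 in 17 to 19 of 20 genes in each of the 7 groups. The mitochondrial share of replicates 1 and 2 was 2.73% and 0.808% in uncompressed HepG2, 3.02% and 1.72% in HepG2 under the weight, 2.70% and 2.00% in uncompressed Hep3B, 3.03% and 1.99% in Hep3B under the weight and 3.60% and 1.83% in Hep3B in 3% PEG. Endothelial markers had 4 rises and 1 fall among 6 tested genes in HepG2 in 4% PEG, with a median of 2.13, or 1.91 with genes near 0 counts at their bounds (camera adjusted p = 0.142, fry adjusted p = 0.000122). Fibroblast markers had 1 rise and 1 fall among 8 tested genes in 4% PEG, and blood cell markers 2 rises and 1 fall among 5.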
